A study of Mus musculus with 27 samples.

How the data were processed

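Total RNA of differentiating mouse embryonic stem cells was measured on Affymetrix mouse expression arrays, 1 array per culture. The cells were of the AB2.2 line. They carried a lentivirus that expresses enhanced green fluorescent protein together with a short hairpin RNA (shRNA), a small RNA that lowers the messenger RNA it matches. In 1 arm the shRNA was directed against Sox17. In the control arm it was directed against firefly luciferase, a gene mouse cells do not have. Per the labels, transduced cells were sorted by flow cytometry on the fluorescent protein, aggregated into embryoid bodies in hanging drops, and moved to culture plates after 4.5 days. RNA was extracted with TRIzol and RNeasy reagents and labelled with biotin, per the labels' protocols. Arrays were run for 7 days of differentiation, from day 0 to day 10, of which days 5, 6, 8 and 10 lie after plating. The labels describe the 2 arrays of a group as biological replicates. The Sox17 shRNA arm had 1 array at day 0, because the labels record its other replicate as failed.

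The deposited values are log2 expression values, 1 per probe set and array, for 45101 probe sets and 27 arrays. Per the submitters' processing notes they were made with RMA, which corrects background, quantile-normalizes probes between arrays and summarises the probes of a set on the log2 scale. Its version, and whether all arrays were run together, are not given in the sources used here. Every value was positive (2.67 to 14.5), and array medians lay between 5.50 and 5.56. Quantile normalization sets all arrays to 1 distribution, so a change of total RNA per cell leaves no trace in these values, and differences are relative to the other genes of an array. RMA values of a silent gene level off near the background of its probes, so folds against a low level are understated.

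Probe sets were named through the platform's annotation table, which gives 34958 of them 1 gene symbol and 932 several, while 9211 are not listed there. Symbols were checked through gene identifiers against the RefSeq gene table of GRCm38.p6, and 0 were changed. Probe sets with a single symbol were kept when they exceeded the median of all values (5.53) in at least 2 arrays (23536 probe sets). Each gene was then represented by its probe set with the highest mean over the 27 arrays, which left 13297 genes. Of the genes named for the average over days 4 to 10, 57 had over 1 probe set with a single symbol, counted before the filter. Of these, 4 had probe sets of both signs on average over those days (Pax6, Tap1, Mybl2 and Foxm1).

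Differences were tested with limma 3.58.1 in R 4.3.3. A mean was fitted for each of the 14 groups (arm by day) to all 27 arrays together, with 13 residual degrees of freedom, and variances were moderated with an intensity trend (prior degrees of freedom 4.68). All p-values are two-sided, from limma, and were adjusted by the method of Benjamini and Hochberg over the 13297 genes of a comparison. Genes with an adjusted p below 0.05 are called changed. The comparisons were the Sox17 shRNA arm minus the control arm at each of the 7 days, the mean of that difference over days 4, 5, 6, 8 and 10 (10 arrays against 10), a moderated F test of whether the difference at these 5 days departed from that at day 2, and each later day of the control arm minus its day 0. Where 1 arm had a single array, its spread was taken to be that of the other groups. The fit, and the assignments of arrays used further on, treat arrays of different days as independent. The labels do not say whether the replicates are separate transductions. If populations differ in a way that lasts over the days, the SE and p-values of averages over days are too small. Standard errors (SE) are those of the moderated fit, and standard deviations (SD) are between replicates.

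Before the data were examined, 27 gene lists were fixed: pluripotency, primed epiblast, primitive streak and early mesoderm, definitive endoderm, visceral endoderm, basement membrane with parietal endoderm, secreted antagonists, Wnt pathway targets, cardiac progenitors, cardiac contractile genes, haematopoietic cells, endothelial cells, neural ectoderm, surface ectoderm, trophoblast, fibroblasts and mesenchyme, smooth muscle, interferon response, p53 targets, proliferation, hypoxia and glycolysis, unfolded protein and heat stress, the Nodal and activin pathway, the Bmp and Notch pathway, the Sox family, Hox clusters, and ribosomal proteins. Some genes stand in several lists. Each list was tested against all other genes with limma's camera at its preset correlation of 0.01, adjusted over the 27 lists. Camera with a correlation estimated from the data, and limma's fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, were run beside it. Counts of list members are given over all genes tested and adjusted over the list alone.

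The genes named in the text follow a rule fixed at the same time. Sox17, Hhex and Cer1 are always given. For the average over days 4 to 10 they are the 12 largest rises and 12 largest falls among called genes with the same sign at all 5 days. For a single day they are the 3 largest rises and falls among called genes whose arrays do not overlap between arms. For the control arm they are the 5 largest rises and falls at days 4 and 10 and the 2 largest at other days. For the F test they are the 6 smallest p-values, and for each list up to 4 members with the largest absolute difference on average, or change from day 0. Symbols that are only clone or predicted-gene names were passed over.

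The fit was tested on simulated data for 13297 genes. In these, 200 genes were changed by known amounts at days 4 to 10 and 200 others at days 8 and 10 only. The contractile list was shifted as well. For the average over days 4 to 10 it recovered 94.0% of genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2. For day 10 alone it recovered 25.4%, 97.0% and 98.5%. For the F test, with genes changed at days 8 and 10 only, it recovered 10.4%, 79.1% and 100%. Of the genes called, 4.24% were unchanged genes for the average and 3.38% for the F test. A simulated shift of the contractile list by -0.5 was the 1 list called by camera at either correlation, and fry called 4 lists. The simulated noise was independent between genes, with 1 variance per gene in all groups. Such data do not show how the list tests or the shares of unchanged genes behave where genes vary together or the arms differ in spread.

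Alternatives fixed before the data were examined were no filter or a stricter filter (the 60th percentile), other ways to choose a gene's probe set, renewed quantile normalization or centring of arrays, no intensity trend, array weights, a log2 difference of at least 1, the replicate number as a block, a fit with only the arrays compared, and leaving out each array in turn. Alternatives added after seeing the data were a term for hybridisation batch, leaving out 3 arrays with a high spike-in signal, leaving out the 2 arrays with the highest 3' to 5' difference, the average over days 6 to 10, and the average less the difference at day 2. The hybridisation term marked the arrays of days 0 and 2 and replicate 1 of day 4. Only the replicates of day 4 inform it, so it also carries any other difference between them. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 in Python 3.11.15. The number of arrays, 2 per group, limits the precision of every value at a single day.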

Results

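Gene expression was followed over 10 days while mouse embryonic stem cells formed embryoid bodies, aggregates in which the 3 germ layers and later beating heart muscle arise. Cells with a short hairpin RNA (shRNA) against Sox17, an endoderm transcription factor, were set beside cells with an shRNA against luciferase, the control. The series asks, by its title, whether Hhex and Cer1 act in the pathway by which Sox17 promotes cardiac mesoderm. The 27 arrays fell into 14 groups of arm and day, with 2 biological replicates in each except for a single Sox17 shRNA array at day 0. Correlations between replicate arrays over all genes lay between 0.964 and 0.998. Replicates differed more in the Sox17 shRNA arm, where the SD over genes of the difference between replicates was 0.26 to 0.51 on the log2 scale, against 0.10 to 0.34 in the control arm. The 3' to 5' difference of the actin and Gapdh control probe sets, a sign of RNA integrity, lay between 0.33 and 0.86 and between -0.31 and 0.12. It was highest in both on Sox17 shRNA replicate 2 of day 4 (0.862 and 0.121) and of day 6 (0.753 and 0.101), and at most 0.548 and 0.025 on the others.

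Control signals, that of hybridisation among them, differed between arrays in a way that followed the day. The signal of the bioB spike-in, bacterial RNA added before hybridisation, was at least 9.26 (log2) on the arrays of days 0 and 2 and of replicate 1 at day 4 in both arms. It was 8.12 on replicate 1 of the Sox17 shRNA arm at day 5, and at most 7.48 on the others. An 18S ribosomal RNA control probe set read 8.77 to 10.84 at days 0 and 2 and 8.18 to 8.67 on replicate 1 of day 4. It read 6.73 to 7.49 on replicate 2 of day 4 and 5.60 to 7.30 at days 5 to 10. The difference may thus not be of hybridisation alone. In the spike-in signal the arms were balanced at each day except day 5. In the control arm, by contrast, the comparison of day 0 with days 5 to 10 coincided with both signals.

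Sox17 itself was lower in the Sox17 shRNA arm on average over days 4 to 10, 3.99-fold, with a log2 difference of -2.00 (SE 0.36, n = 10 arrays per arm, limma adjusted p = 3.63e-04). Its log2 level was near background at day 0 in both arms (3.75 and 3.92 in control arrays, 3.69 with Sox17 shRNA) and reached 10.30 and 10.66 in control arrays at day 4. The Sox17 shRNA arrays of day 4 read 5.53 and 9.39, those of day 5 read 7.77 and 10.08, those of day 6 read 8.60 and 9.39, those of day 8 read 7.90 and 8.54, and those of day 10 read 6.71 and 7.19. Control arrays read 10.38 and 10.38 at day 5 and 9.83 and 9.355 at day 6, so Sox17 shRNA replicate 2 lay near the control at these days. The fall passed the test at day 4 (8.12-fold, -3.02, SE 0.80, adjusted p = 0.0377) and day 10 (8.18-fold, -3.03, adjusted p = 0.0205). The differences at day 2 (-1.29), day 5 (-1.45, adjusted p = 0.307), day 6 (-0.60, adjusted p = 0.835) and day 8 (-1.88, adjusted p = 0.25) did not. At day 4, where the replicates also differed in spike-in signal, the difference within arrays of like signal was -4.77 for replicate 1 and -1.27 for replicate 2. The day 4 call was lost without control replicate 1 (adjusted p = 0.11), control replicate 2 (0.155) or Sox17 shRNA replicate 1 (-1.09, 0.292), while without Sox17 shRNA replicate 2 the difference was -4.95 (adjusted p = 1.1e-04), and the day 10 call without any 1 of its 4 arrays (adjusted p from 0.0565 to 0.135). The other Sox17 probe set gave an average of -1.75.

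Cer1, a secreted antagonist of Nodal, Bmp and Wnt signals made by anterior endoderm, fell at day 4 by 8.72-fold (-3.12, SE 0.60, adjusted p = 0.00683), from a log2 level of 9.05 in control arrays to 5.92. The day 5 difference of -1.77 missed the threshold (adjusted p = 0.0721), and the differences at days 6, 8 and 10 were -0.10, -0.11 and -0.16. The average over days 4 to 10 was -1.05 (SE 0.27, adjusted p = 0.00621), while that over days 6 to 10 was -0.12 (adjusted p = 0.866). Hhex, a homeobox repressor of anterior endoderm and blood progenitors, was 1.56-fold lower on average (-0.64, SE 0.20, adjusted p = 0.0245), while the differences at day 2 (1.04, adjusted p = 0.302), day 4 (-1.38, adjusted p = 0.0883) and day 5 (-1.03, adjusted p = 0.178) did not pass the threshold. At day 4 each Sox17 shRNA array was like the control array of the same number in spike-in signal, so leaving out 1 of them unbalances that signal too. Within arrays of like signal the Hhex difference was -2.2 for replicate 1 and -0.56 for replicate 2, and that of Cer1 -4.98 and -1.26. The Sox17 shRNA arrays of that day read 4.26 and 7.58 for Cer1. Its difference was -1.46 (adjusted p = 0.00584) without replicate 1 of that arm, -4.79 (adjusted p = 1.8e-08) without replicate 2, whose 3' to 5' difference was high, and the call was lost without control replicate 1 (-2.92, adjusted p = 0.0559). At day 5 Cer1 passed without Sox17 shRNA replicate 2 (-2.26, adjusted p = 0.0487). Hhex passed at day 4 without Sox17 shRNA replicate 2 (-2.43, adjusted p = 5.7e-04), and its difference was -0.33 without replicate 1. The average Hhex call was lost without control day 4 replicate 2 (adjusted p = 0.053), control day 6 replicate 1 (0.055), Sox17 shRNA day 5 replicate 1 (0.061) or Sox17 shRNA day 8 replicate 2 (0.055), and over days 6 to 10 the Hhex difference was -0.26 (adjusted p = 0.568). With the day 2 difference subtracted, a comparison added after seeing the data, neither average passed (Cer1 -1.13, adjusted p = 0.549, and Hhex -1.68, adjusted p = 0.0941).

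**Figure D1:**
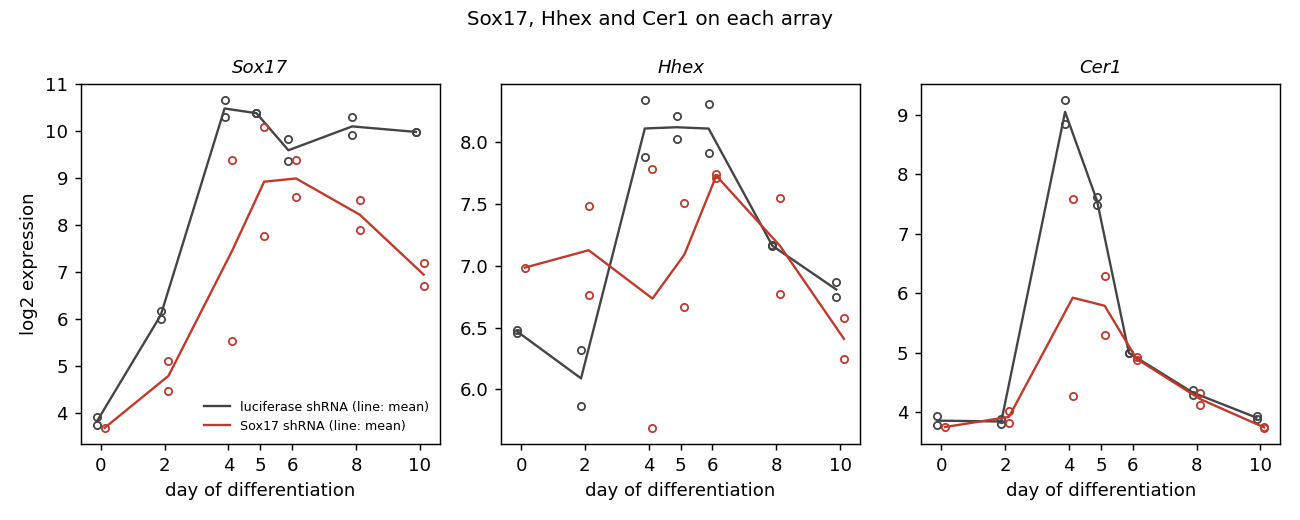
Log2 expression of Sox17, Hhex and Cer1 (vertical axis) by day of differentiation (horizontal axis), with points for single arrays and lines through the group means of the control and Sox17 shRNA arms. Sox17 rose in control arrays to 10.30 and 10.66 at day 4, and the 2 Sox17 shRNA arrays of that day lay at 5.53 and 9.39.

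The control arm shows what the differentiating cells passed through. By day 4 the pluripotency list had fallen, with 19 of its 24 measured members lower than at day 0 (21 adjusted over the list alone) and none higher. Nr0b1 fell 82.3-fold (-6.36, SE 0.24) and Zfp42 38.8-fold. Primitive streak and early mesoderm genes rose, 15 of 20 (16 adjusted over the list alone) with 1 lower, among them Lhx1 (log2 difference 6.22), Mixl1 (5.54) and Eomes (5.09), transcription factors of gastrulation. Of 24 definitive endoderm genes 16 rose (17 adjusted over the list alone), among them Sox17 itself (100.4-fold), Cer1 (36.5-fold) and the chemokine receptor Cxcr4 (35.2-fold), and of 21 cardiac progenitor genes 12 rose and 1 fell (the same adjusted over the list alone), with Mesp1 at 4.58. The single genes with the largest rises at day 4 were Amot, which encodes angiomotin (277-fold), the apelin receptor Aplnr (193-fold), the cadherin Cdh2 (109-fold), Sox17 and Fgf5 (90.0-fold), and Mymx, Nr0b1, Triml1, Fbxo15 and Morc1 fell most (-6.44 to -5.96). Camera gave adjusted p-values of 2.6e-11 for pluripotency, 1.2e-07 for the streak, 3.9e-06 for endoderm and 0.00134 for cardiac progenitors, and with an estimated correlation none of these passed (adjusted p = 0.226, 0.316, 0.316 and 0.48).

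By day 10 the control cells expressed the contractile apparatus of heart muscle. Of 29 cardiac contractile genes 28 rose and 1 fell, with the same counts adjusted over the list alone. Actc1, cardiac actin, rose 183-fold (7.51, SE 0.20), Tnnt2, cardiac troponin T, 151-fold (7.24, SE 0.16), and Myh6, the atrial myosin heavy chain, 129-fold. Fibroblast genes (18 higher, 1 lower of 22) and basement membrane genes (18 higher, 1 lower of 20) rose as well, led by Col3a1 (490-fold), which had the largest change of any gene, and by Col4a2 (92.7-fold). Cdh11, a mesenchymal cadherin, rose 230-fold and Ttr, transthyretin of visceral endoderm and liver, 151-fold. Cardiac progenitor genes (16 higher of 21, Tbx20 5.68, Hand2 5.35), smooth muscle genes (11 of 13), Bmp and Notch pathway genes (22 of 27) and visceral endoderm genes (16 higher, 2 lower of 21) were higher, and all 24 pluripotency genes were lower, Tdgf1 by 77.5-fold and Nanog by 52.6-fold. These counts were the same adjusted over the list alone. Proliferation genes fell, 25 of 27 (26 adjusted over the list alone). The contractile rise passed camera at both correlations (adjusted p = 4.5e-15, and adjusted p = 0.00411 with an estimated correlation). The others passed with the preset value alone: with an estimated correlation the adjusted p was 0.0896 for pluripotency, fibroblasts and smooth muscle, 0.135 for basement membrane and cardiac progenitors, 0.329 for Bmp and Notch, 0.346 for visceral endoderm and 0.486 for proliferation.

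Between these days, Fgf5 (50.8-fold) and Cubn (45.7-fold) rose most at day 2 and Lrrc34 and Mymx fell most. Amot and Aplnr led at day 5, Amot and Tnnt2 (7.28) at day 6, and Col3a1 (8.39) and Actc1 (7.89) at day 8. Morc1, a gene of germ cells and stem cells, was among the largest falls from day 4 to day 10 (-7.13 at day 8), with Klf2 at day 5 (-6.85) and Zfp42 at days 6 and 8. The number of genes that differed from day 0 was 4263 at day 2 (2212 higher, 2051 lower), 6134 at day 4 (2995, 3139), 7630 at day 5 (3335, 4295), 8393 at day 6 (3736, 4657), 9597 at day 8 (4239, 5358) and 9509 at day 10 (4187, 5322). Among those at least 2-fold apart the balance was the other way, with 564 higher and 636 lower at day 2, 1160 and 961 at day 4 and 2240 and 1762 at day 10. From day 5 on the median of all genes lay 0.11 to 0.14 log2 units lower than at day 0 (-0.12 at day 5, -0.13 at day 10). With a term for hybridisation, added after seeing the data, it was -0.016 at day 5, -0.027 at day 6 and -0.082 at days 8 and 10. That term rests on replicate 1 against replicate 2 of day 4 alone, so hybridisation is not separated from other differences between them. Within arrays of like spike-in signal, day 4 replicate 1 minus day 0 gave list medians of 2.56 for the streak, 2.01 for endoderm and -3.16 for pluripotency, and day 10 minus day 4 replicate 2 gave 3.32 for contractile genes, 2.36 for fibroblasts and 1.51 for basement membrane.

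The arms were first compared before and early in differentiation. At day 0, when Sox17 was near background in both arms, 251 genes differed (150 higher, 101 lower with Sox17 shRNA), against 1 array of that arm. Of those at least 2-fold apart 35 were higher and 57 lower. Gadd45g, a growth arrest gene, was 4.86-fold higher (2.28, SE 0.49, adjusted p = 0.0186), Fgfbp1, a carrier of fibroblast growth factors, 3.63-fold, and Pdia4, a disulfide isomerase of the endoplasmic reticulum, 2.99-fold. Rpl39l, a ribosomal protein variant of germ cells, was 8.00-fold lower (-2.999, SE 0.24, adjusted p = 1.8e-06), Hormad1, a meiotic chromosome protein, 7.66-fold, and Serpinb6c 6.75-fold. The Gadd45g call was lost without control replicate 1 (adjusted p = 0.0809) or 2 (0.0948), and the Pdia4 call without control replicate 2 (0.136). By camera 0 of the 27 lists passed at day 0, with 3 at an unadjusted p under 0.05, and fry gave 0 and 2.

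At day 2, 338 genes differed (206 higher, 132 lower), of which 26 higher and 52 lower by at least 2-fold. Rpl39l was again lower (8.29-fold, -3.05, SE 0.20, adjusted p = 1.7e-07), with Fst, which encodes the activin antagonist follistatin (5.75-fold, adjusted p = 0.0101), and the interferon-induced gene Ifi35 (5.50-fold). Sox18 (3.40-fold) and Fli1 (3.37-fold), both endothelial transcription factors, and Nap1l5 (3.24-fold) were higher. Basement membrane genes were the 1 list that passed, with 6 of 20 lower and none higher (10 lower adjusted over the list alone). The laminin chain Lama1 was lowest among its named members (-2.28, adjusted p = 0.0186), and the list median was -0.60 (adjusted p = 1.7e-08, and adjusted p = 0.553 with an estimated correlation). Without any 1 of the 4 arrays Sox18 (adjusted p from 0.0785 to 0.277), Fli1 (0.0673 to 0.391) and Fst (0.076 to 0.0885) no longer passed, nor did Nap1l5 without control replicate 1 (0.137), Sox17 shRNA replicate 1 (0.0698) or replicate 2 (0.0715).

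At day 4, when Sox17 peaked in the control, 684 genes differed (443 higher, 241 lower), of which 78 higher and 90 lower by at least 2-fold. Without Sox17 shRNA replicate 2, which had a high 3' to 5' difference, the list medians were -1.39 for endoderm, -0.43 for cardiac progenitors and 0.47 for pluripotency. The streak median was then -0.43, against 0.06 with all arrays, and that of Bmp and Notch genes -0.57, against -0.22. The array left, with a spike-in signal of 9.71, was set against controls of 9.55 and 7.08. This leave-out therefore does not separate RNA integrity from hybridisation. Definitive endoderm genes were lower, 8 of 24 with none higher (14 adjusted over the list alone, median -0.88), including Cer1, Sox17, the pioneer factor Foxa1 (-2.44) and the secreted inhibitor Spink1 (-3.05). Cardiac progenitor genes were lower, 7 of 21 (8 adjusted over the list alone, median -0.32), with Gata4, a heart and endoderm transcription factor, at -1.68 (adjusted p = 0.00523). Pluripotency genes were higher, 7 of 24 (9 higher and 1 lower adjusted over the list alone, median 0.64), with Zfp42 at 2.23 and Dppa3 at 2.38. Nkx1-2, a homeobox gene of the streak and tail bud, rose most (8.28-fold, 3.05, SE 0.24, adjusted p = 3.1e-06), then Car3, a carbonic anhydrase (6.12-fold), and Srgn, the proteoglycan serglycin, fell most (9.65-fold, adjusted p = 0.0408). By camera the adjusted p was 3.7e-09 for endoderm, 4.3e-06 for cardiac progenitors and 6e-05 for pluripotency, and with an estimated correlation the adjusted p was 0.283, 0.301 and 0.374. Car3 no longer passed without control replicate 1 (adjusted p = 0.0512) or 2 (0.0631), Dppa3 without either control replicate or Sox17 shRNA replicate 1 (0.0729 to 0.0749), and Srgn and Spink1 without either control replicate (0.126 to 0.169) or Sox17 shRNA replicate 2 (0.216 and 0.19).

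At day 5, after plating, 1249 genes differed (818 higher, 431 lower). Primitive streak genes were higher, 9 of 20 with none lower (12 higher and 2 lower adjusted over the list alone), with a list median of 0.87. Mixl1, a homeobox gene of the streak, was 17.5-fold higher (4.13, SE 0.37, adjusted p = 4.6e-06), by 4.40 in replicate 1 and 3.85 in replicate 2 against the control mean, and Evx1 was higher by 2.48. Wnt pathway targets were higher too, 7 of 13 (8 higher and 1 lower adjusted over the list alone), with cyclin D1, Ccnd1, at 1.24. Tagln, transgelin of smooth muscle and early mesoderm, was 8.57-fold higher (adjusted p = 1.1e-04) and the embryonic globin Hbb-y 25.4-fold (4.67, SE 1.22, adjusted p = 0.0227). Srgn (17.6-fold), Klhl4 (10.6-fold) and Alx1, a homeobox gene of mesenchyme (8.60-fold, -3.10, SE 0.22), were lowest. By camera the adjusted p was 2.2e-07 for the streak and 2.0e-04 for Wnt targets, and with an estimated correlation the adjusted p was 0.329 and 0.182. The Hbb-y call was lost without control replicate 1 (adjusted p = 0.138), control replicate 2 (0.103) or Sox17 shRNA replicate 1 (2.01, 0.429), its difference was 7.33 without Sox17 shRNA replicate 2 (adjusted p = 3.0e-04), and the Srgn call without control replicate 1 (0.0599) or 2 (0.0517).

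At day 6, 691 genes differed (377 higher, 314 lower, and 81 and 145 by at least 2-fold), and heart muscle genes had become the lowest. Without Sox17 shRNA replicate 2, which had a high 3' to 5' difference, 652 genes differed and the contractile median was -1.84, and 900 genes differed when replicate 2 of day 4 was left out as well. Myl7, the atrial myosin light chain, was 96.3-fold lower (-6.59, SE 0.37, adjusted p = 1.3e-09), Tnnt2 57.5-fold (-5.85, SE 0.16, adjusted p = 4.5e-14) and the myosin light chain Myl4 43.0-fold (-5.42, SE 0.23). Of 29 contractile genes 19 fell and none rose, also adjusted over the list alone, with a list median of -1.70 (adjusted p = 2e-45, and adjusted p = 1.3e-05 with an estimated correlation). Cardiac progenitor genes fell, 6 of 21 with 1 higher (10 and 1 adjusted over the list alone), among them the muscle regulators Myocd (-3.52, SE 0.21) and Mef2c (-3.32), with an adjusted p of 2.1e-09 and an adjusted p = 0.0604 with an estimated correlation. Nkx1-2 (6.84-fold), the collagen chain Col1a1 (4.61-fold) and the antisense transcript Hoxd3os1 (4.59-fold) were highest, and 9 of 23 Hox genes rose with none lower (10 adjusted over the list alone, adjusted p = 3.0e-09, and adjusted p = 0.0549 with an estimated correlation). Hoxd3os1 no longer passed without control replicate 1 (adjusted p = 0.0552) or Sox17 shRNA replicate 1 (1.44, 0.068).

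At day 8, 641 genes differed (251 higher, 390 lower). Contractile genes fell in 24 of 29 (26 adjusted over the list alone), with a list median of -2.74 (adjusted p = 3.7e-67, and adjusted p = 1.2e-06 with an estimated correlation). Myl2, the ventricular myosin light chain, was 69.3-fold lower (-6.11, SE 0.48, adjusted p = 9.8e-08), Srgn 52.9-fold and Myh6 39.4-fold (-5.30, SE 0.15). Blood genes were higher, 9 of 20 with none lower (11 higher and 1 lower adjusted over the list alone). Nfe2, an erythroid and megakaryocytic transcription factor, rose 6.72-fold (2.75, SE 0.38, adjusted p = 1.3e-04), and Alas2, the erythroid enzyme of haem synthesis, 6.69-fold. The blood list had a median of 0.96 (adjusted p = 5.3e-10, and adjusted p = 0.118 with an estimated correlation). Tbx4, a T-box factor of hindlimb, allantois and lung mesenchyme, was 5.55-fold higher (2.47, SE 0.21, adjusted p = 2.8e-07).

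At day 10, 1330 genes differed (747 higher, 583 lower, and 190 and 241 by at least 2-fold). Contractile genes were lower in 25 of 29 (26 adjusted over the list alone, median -2.49, adjusted p = 1.2e-49, and adjusted p = 7.5e-06 with an estimated correlation), with Myl2 22.7-fold lower. Srgn (44.8-fold, -5.49, SE 0.88) and Igfbp1, an insulin-like growth factor binding protein of liver and decidua (35.0-fold, -5.13, SE 0.23, adjusted p = 1.9e-10), were lower by more. Hbb-y (26.3-fold, SE 1.22), Tbx4 (12.2-fold, 3.60, SE 0.21, adjusted p = 3.1e-09) and the embryonic globin Hba-x (11.9-fold, SE 1.07) were highest. Neural ectoderm genes fell, 8 of 25 with 2 higher (11 and 2 adjusted over the list alone), with the eye and forebrain factors Six3 at -2.07 and Pax6 at -2.04 (adjusted p = 1.7e-05, and adjusted p = 0.0068 with an estimated correlation). The Sox family fell in 6 of 17 members with 2 higher, also adjusted over the list alone (adjusted p = 0.00123, and adjusted p = 0.0219 with an estimated correlation), with Sox7 at -2.68. Fibroblast genes rose in 11 of 22 (12 adjusted over the list alone), with Col1a2 at 1.70 and Fbln2 at 1.53, and visceral endoderm genes fell in 10 of 21 (15 adjusted over the list alone). The last 2 lists had an adjusted p of 1.8e-08 and 1.0e-11, and an adjusted p = 0.056 each with an estimated correlation. Without control replicate 1 or 2 or Sox17 shRNA replicate 1, neither Hbb-y (adjusted p = 0.11, 0.111 and 0.145) nor Hba-x (0.185, 0.185 and 0.323) passed.

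**Figure D2:**
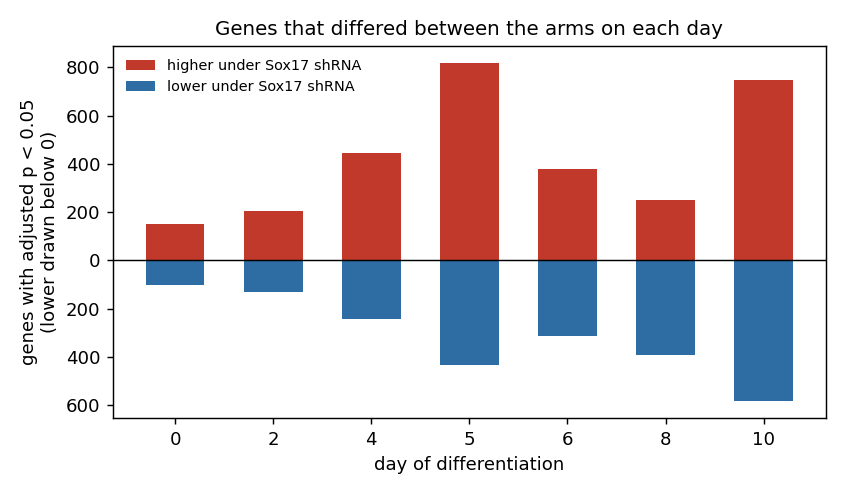
Number of genes called higher (bars above 0) or lower (bars drawn below 0) with Sox17 shRNA than in the control (vertical axis) at each day (horizontal axis), at a limma adjusted p below 0.05. The counts range from 251 genes at day 0 to 1330 at day 10.

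The counts for single days rest on few arrays, and most moved by over 1.5 times when 1 was left out. Without control replicate 1 or 2 of the same day they were 152 and 76 at day 0, 68 and 127 at day 2, 216 and 275 at day 4, 315 and 526 at day 5, 229 and 381 at day 6, 309 and 316 at day 8, and 540 and 565 at day 10. Without Sox17 shRNA replicate 1 they were 152 at day 2, 328 at day 5, 423 at day 6, 390 at day 8 and 743 at day 10. Without replicate 2 they were 85 at day 2 and 1217 at day 4. They moved by less without replicate 1 of that arm at day 4 (643) and replicate 2 at days 5, 6, 8 and 10 (1710, 652, 704 and 1007). With only the arrays of the day limma called 0 genes at day 4 (1034 at an unadjusted p under 0.05), so that none of those named there passed, and 2111, 798, 244, 328 and 335 at days 0, 2, 5, 6 and 8. With array weights it called 10 at day 4 (906 at an unadjusted p under 0.05) and 1242, 821, 1063 and 2866 at days 0, 2, 8 and 10. With a term for hybridisation, added after seeing the data, they were 536 at day 0, 583 at day 2 and 1103 at day 4. Without the 3 arrays of days 4 and 5 with a high spike-in signal, left out after seeing the data, 352 genes were called at day 4 and 660 at day 5. The share of higher genes among those called turned at several days. It was 39.5% at day 0 without control replicate 2 (59.8% with all arrays) and 49.1% with each gene's most variable probe set. At day 2 it was 38.2% without control replicate 1, and 46.7% and 42.4% without Sox17 shRNA replicate 1 or 2 (61.0% with all). At day 4 it was 77.1% without Sox17 shRNA replicate 1 and 45.6% without replicate 2 (64.8% with all). At day 6 it was 47.6% and 42.3% without control replicate 1 or 2, 46.6% without Sox17 shRNA replicate 1 and 41.5% with only the arrays of the day (54.6% with all), and at day 10 47.6% without Sox17 shRNA replicate 1 (56.2% with all). When arrays were quantile-normalized again, 55.2% of the genes called at day 5 were higher, against 65.5% in the values as deposited, and with arrays centred on their medians 65.3% at day 6, against 54.6%.

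Of the 21 pairs of days, which share no arrays, days 8 and 10 resembled each other most. Across genes, which are not independent replicates, the differences correlated at 0.797 between them, 0.674 between days 6 and 8, 0.639 between days 4 and 5, 0.592 between days 6 and 10, 0.467 between days 5 and 6 and at most 0.343 in the other pairs, which included the neighbouring days 2 and 4 (0.305). Those of day 0 correlated with the other days at 0.0645 to 0.340. Days 8 and 10 had 198 genes called higher at both, where independent lists would share 14.1, and 287 called lower at both, against 17.1. The F test of whether the difference at days 4 to 10 departed from that at day 2 called 798 genes. Its 6 smallest p-values belonged to genes expressed in heart muscle: Myh6 (adjusted p = 8.5e-12), Tnnt2 (1.6e-11), Sphkap, Tecrl, Smpx and Myl4. Without control day 10 replicate 2 the F test called 529 genes, and without Sox17 shRNA day 4 replicate 2 it called 1244.

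The average over days 4 to 10 (10 arrays per arm) gave the most precise comparison, with 3593 genes changed, 1970 higher and 1623 lower, of which 51 and 117 by at least 2-fold. The sign was the same at all 5 days for 2451 of them (1405 higher, 1046 lower). The largest falls were in Srgn, serglycin (25.7-fold, -4.68, SE 0.40, adjusted p = 1.2e-07), and in the heart muscle genes Myl7 (11.8-fold, -3.56, SE 0.16), Myh6 (8.46-fold, -3.08, SE 0.07, adjusted p = 1.3e-15) and Myl2 (7.21-fold, -2.85, SE 0.21). Lama1 (7.01-fold), the endocytic receptor Cubn of visceral endoderm (6.64-fold), the imprinted neuronal gene Nnat (5.92-fold), the cardiac splicing regulator Rbm24 (4.85-fold), Nxf3, Pga5, Klhl4 and Sox17 (4.60- to 3.99-fold) followed. The largest rises were in Hbb-y (8.26-fold, 3.04, SE 0.55, adjusted p = 3.6e-04), Nkx1-2 (4.48-fold, 2.16, SE 0.11, adjusted p = 1.2e-10), the pluripotency marker Zfp42 (3.77-fold), Tbx4 (3.24-fold, SE 0.09), Dppa3 (3.06-fold), Mbnl3, Parp12, Pdgfrl, Hoxd3os1 (3.0- to 2.76-fold), Nanog (2.68-fold, SE 0.28, adjusted p = 7.3e-04), Morc1 and Hoxc8 (2.46- and 2.40-fold).

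For some genes part of the average was present at day 2, when Sox17 read 6.01 and 6.17 in control arrays and 5.12 and 4.48 with Sox17 shRNA. Of the 24 genes named by size 3 were called at that day: Lama1 (-2.28), Myh6 (-0.95) and, opposite to its average, Morc1 (-1.91). With the difference at day 2 subtracted, a comparison added after seeing the data and with a larger SE, 313 genes were called (155 higher, 158 lower). Of the 24 genes named by size, 12 still passed, among them Nkx1-2, Tbx4, Pdgfrl, Hoxc8, Myl7, Myh6, Myl2 and Rbm24. Srgn (-1.98, adjusted p = 0.431), Lama1 (-0.53, adjusted p = 0.816), Sox17 (-0.70, adjusted p = 0.855) and Hbb-y (3.02, adjusted p = 0.361) were among the 12 that did not. Hbb-y and Nanog (1.39, adjusted p = 0.425) each differed by 0.03 at day 2, so that the larger SE took away their calls. For a gene near background at day 2 the subtraction takes nothing away, so a call kept there says little of earlier differences. Over days 6 to 10 alone 23 of the 24 passed, all but Nnat (adjusted p = 0.147). The Nnat call was also lost without any 1 of the 10 control arrays or without replicate 1 of the Sox17 shRNA arm at any of the 5 days (adjusted p from 0.0507 to 0.0824).

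**Figure D3:**
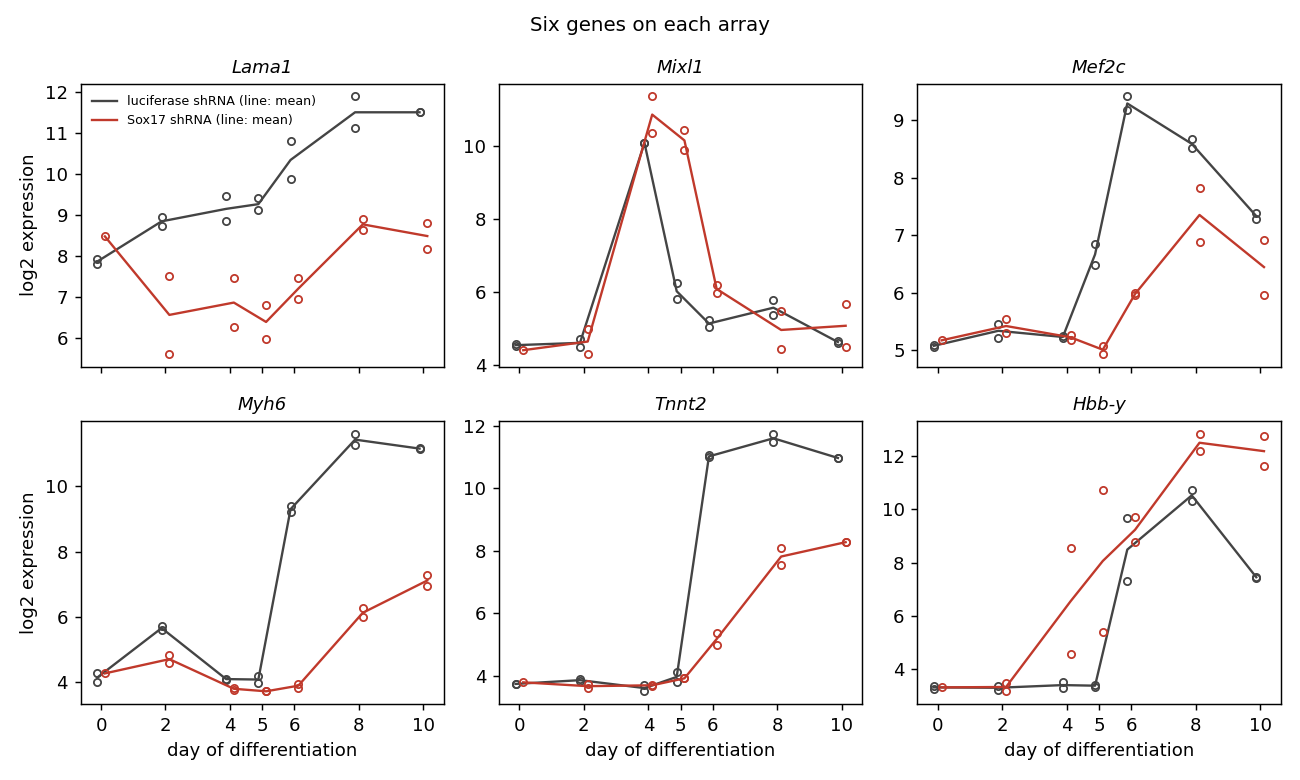
Log2 expression (vertical axis) of 6 genes by day of differentiation (horizontal axis), with points for single arrays and lines through group means of the control and Sox17 shRNA arms. Myh6 was 39.4-fold lower with Sox17 shRNA at day 8 and Mixl1 17.5-fold higher at day 5.

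On average over days 4 to 10, the lists of the heart and the endoderm were lower. Cardiac contractile genes fell in 26 of 29 with none higher (27 adjusted over the list alone, median -1.27, Ttn, the giant spring protein titin, -2.47), the 1 list that passed camera at both correlations (adjusted p = 1.1e-33, and adjusted p = 6.8e-05 with an estimated correlation). Of these 29, 27 were lower over days 6 to 10 and 20 with the day 2 difference subtracted. A gene near background at day 2, as Tnnt2 was (3.83 and 3.88 in control arrays), has no difference there to subtract. Cardiac progenitor genes fell in 10 of 21 with 1 higher, also adjusted over the list alone (median -0.39): Myocd at -1.60, Mef2c at -1.42 and Gata4 at -1.06 fell, and Hand1, a factor of heart and extraembryonic mesoderm, rose (1.01). Definitive endoderm genes fell in 15 of 24 with 1 higher (16 and 1 adjusted over the list alone, median -0.59, Spink1 -1.67, Otx2 -1.67, Foxa1 -1.15). Visceral endoderm genes fell in 15 of 21, also adjusted over the list alone (median -0.89, Rhox5 -1.77, S100g -1.75, Amn -1.70), and basement membrane genes in 12 of 20 (15 adjusted over the list alone, median -0.68, Lama1 -2.81, the parathyroid hormone receptor Pth1r -1.61). Camera gave an adjusted p of 1.2e-06 for cardiac progenitors, 7.4e-08 for definitive endoderm, 1.0e-08 for visceral endoderm and 2.2e-09 for basement membrane, and an adjusted p = 0.105 for each with an estimated correlation. Basement membrane was not called with the day 2 difference subtracted (median -0.12, adjusted p = 0.80), and S100g was then no longer lower.

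Endothelial genes fell in 6 of 23, also adjusted over the list alone (median -0.23, Sox7 -1.35, the sialomucin Emcn -0.70, adjusted p = 0.00416, and adjusted p = 0.492 with an estimated correlation). The endothelial call was lost without Sox17 shRNA day 8 replicate 2 (-0.10, adjusted p = 0.054). Hypoxia and glycolysis genes fell in 11 of 21 with 1 higher (12 and 1 adjusted over the list alone, median -0.34), with Bnip3 at -1.53 and the growth factor Vegfa at -0.88 (adjusted p = 3.3e-06, and adjusted p = 0.277 with an estimated correlation). Bmp and Notch pathway genes fell in 12 of 27 with 3 higher, also adjusted over the list alone (median -0.20), with Id4 at -1.26, the Notch ligand Jag1 at -1.20 and the Notch target Hey1 at -1.15 (adjusted p = 0.00149, and adjusted p = 0.382 with an estimated correlation). The Sox family fell in 5 of 17 with 1 higher, also adjusted over the list alone (median -0.16, adjusted p = 0.0101, and adjusted p = 0.105 with an estimated correlation), and its members that fell included Sox17, which the shRNA targets, Sox7 and Sox21 (-0.56).

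Blood, mesenchyme, Hox and pluripotency genes were higher. Haematopoietic genes rose in 13 of 20 with 1 lower (14 and 1 adjusted over the list alone, median 0.55), led by the embryonic globins Hbb-y, Hbb-bh1 (4.96-fold, 2.31, SE 0.55) and Hba-x (4.23-fold, 2.08, SE 0.48) and by Nfe2 (1.21, SE 0.17). Fibroblast and mesenchyme genes rose in 11 of 22 with 1 lower (13 and 1 adjusted over the list alone, median 0.48, Col1a1 1.20, Fbln2 1.11). Hox genes rose in 12 of 23 with 2 lower (13 and 2 adjusted over the list alone, median 0.31), with the posterior members Hoxc8 at 1.26, Hoxd9 at 1.22, Hoxc10 at 1.09 and Hoxd10 at 1.08. Pluripotency genes rose in 12 of 24 with 2 lower (12 and 4 adjusted over the list alone, median 0.30), Zfp42, Dppa3 and Nanog among those that rose and Klf4 (-1.51) among those that fell. Camera gave an adjusted p of 2.4e-05 for blood, 1.1e-04 for fibroblasts, 3.4e-06 for Hox and 0.00452 for pluripotency, and with an estimated correlation the adjusted p was 0.262, 0.178, 0.105 and 0.382. Over days 6 to 10 alone the pluripotency list was not called (median 0.29, adjusted p = 0.31), nor was the haematopoietic list with the day 2 difference subtracted (median 0.29, adjusted p = 0.058). With that subtraction Klf4 was no longer lower.

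Smaller shifts upward passed in 3 further lists. Interferon response genes rose in 6 of 18 (9 adjusted over the list alone, median 0.17), with Ifit2 at 1.14 and the immunoproteasome subunit Psmb8 at 0.89 (adjusted p = 0.00356, and adjusted p = 0.350 with an estimated correlation). Proliferation genes rose in 7 of 27, also adjusted over the list alone (median 0.13), with the replication helicase subunits Mcm2 at 0.69 and Mcm5 at 0.38 (adjusted p = 0.00324, and adjusted p = 0.538 with an estimated correlation). Trophoblast genes rose in 4 of 10, also adjusted over the list alone (median 0.12, adjusted p = 0.042, and adjusted p = 0.348 with an estimated correlation), namely Hand1, Cdx2 (0.99), Tfap2c (0.69) and Plac1 (0.68), of which Hand1 also marks mesoderm and Cdx2 the posterior streak. The trophoblast call was lost without replicate 1 of the control at days 4, 5 and 6 (adjusted p = 0.086, 0.0597 and 0.0501), Sox17 shRNA replicate 2 at days 4, 5, 6 and 8 (0.121, 0.0727, 0.0806 and 0.0854) or Sox17 shRNA day 10 replicate 1 (0.0515). Without both arrays of high 3' to 5' difference it was lost too (adjusted p = 0.204). The proliferation list was not called over days 6 to 10 (median 0.09, adjusted p = 0.176) or with the day 2 difference subtracted (median 0.079, adjusted p = 0.136).

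The remaining 11 lists did not pass. Primitive streak genes, higher at day 5, had 5 higher and 2 lower of 20 on average (Evx1 1.23, Mixl1 1.14, Pdgfra -0.88, adjusted p = 0.195). Wnt pathway targets had 3 higher and 1 lower of 13 (Nkd1 0.69, Ccnd1 0.58, adjusted p = 0.0838), primed epiblast genes 2 higher and 5 lower of 13 (Cldn6 -1.19, Lefty1 0.81, adjusted p = 0.149), and secreted antagonists 4 higher and 6 lower of 18 (Shisa2 -1.55, Lefty2 0.81, adjusted p = 0.426). Nodal and activin pathway genes had 6 higher and 3 lower of 17 (Nodal 0.79, Gdf3 0.75, adjusted p = 0.393), neural ectoderm genes 5 higher and 4 lower of 25 (Six3 -1.15, Gap43 0.54, adjusted p = 0.318) and smooth muscle genes 6 higher and 1 lower of 13 (Tagln 1.07, Des -0.44, adjusted p = 0.162). Surface ectoderm genes had 2 higher and 2 lower of 14, with a median of 0.01 and a mean of 0.02 while camera's direction was down (Trp63 -0.53, adjusted p = 0.755). Targets of p53 had 5 higher and none lower of 17 (Pmaip1 0.79, Fas 0.44, adjusted p = 0.112), unfolded protein and heat stress genes 2 higher and 1 lower of 18 (Hmox1 0.60, adjusted p = 0.768) and ribosomal proteins 1 higher and 2 lower of 16 (Rps6 0.23, Rps3 -0.08, adjusted p = 0.0876). Adjusted over the list alone these counts were the same except for secreted antagonists (5 higher), the Nodal and activin pathway (4 lower) and unfolded protein genes (none lower). Over days 6 to 10 alone primed epiblast (median -0.20, adjusted p = 0.0212), neural ectoderm (-0.18, adjusted p = 0.0124) and ribosomal proteins (-0.043, adjusted p = 0.0251) passed, and Wnt targets with the day 2 difference subtracted (0.30, adjusted p = 0.017). None of these passed with an estimated correlation (adjusted p = 0.409, 0.113, 0.381 and 0.225). In all, 16 of the 27 lists passed camera on average, 7 up and 9 down, 1 of them with an estimated correlation, and 18 passed fry. Pax6, named among the neural genes at day 10, had probe sets of both signs on average.

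**Figure D4:**
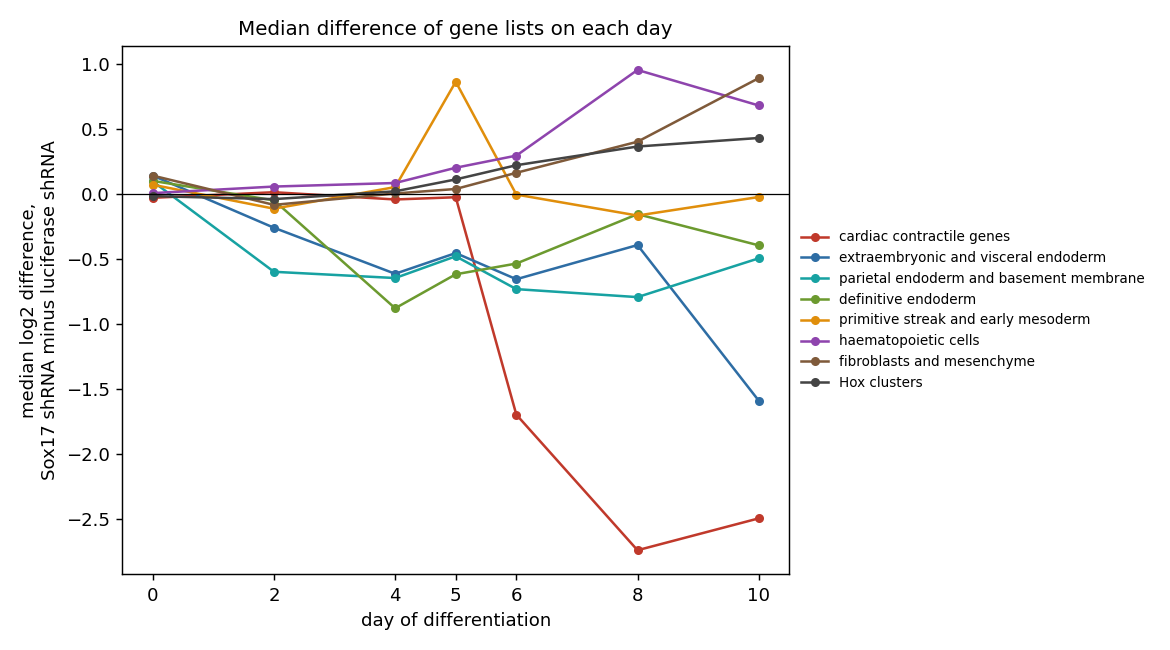
Median log2 difference, Sox17 shRNA minus control, over the members of 8 gene lists (vertical axis, a point per list and day joined by lines) by day of differentiation (horizontal axis). The contractile list reads -1.70, -2.74 and -2.49 at days 6, 8 and 10, and the streak list 0.87 at day 5.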

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

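Of the tests in this part, the comparison of the blood genes with markers of other cell types and the assignments for the day 0 genes were chosen only after the result was seen, and the bound of the first was changed 2 times. A pair of further tests, of the contractile and blood lists at day 2, was set aside after its results were seen, and the day 2 medians are given with each pattern. No group held enough arrays for a test of single outlying arrays.

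The difference between the arms depended on the day, by the F test against day 2, for 798 of all 13297 genes (6.00%) and for 30 of the 52 genes named in the arm comparisons. These were chosen partly for a small p in this test or a large difference at 1 day, so their share says nothing of other genes. The adjusted p was smallest for Myh6 (8.455e-12), Tnnt2 (1.58e-11), Sphkap (4.449e-10), Tecrl (1.348e-09), Smpx (2.957e-09) and Myl4 (3.06e-09). It was 1.909e-08 for Igfbp1, 2.686e-07 for Tbx4, 7.7e-07 for Myl7, 2.03e-06 for Rpl39l, 9.645e-06 for Alx1, 1.077e-05 for Myl2, 2.75e-05 for Nkx1-2 and 8.508e-05 for Pdgfrl. For Ifi35 it was 0.0001189, for Mixl1 0.0001573, for Hoxc8 0.0002081, for Fst 0.0003086, for Col1a1 0.001457, for Tagln 0.00365, for Rbm24 0.008219 and for Nxf3 0.008269. Morc1 (0.01145), Klhl4 (0.01401), Nfe2 (0.01788), Serpinb6c (0.01857), Car3 (0.0212), Parp12 (0.03134), Sox18 (0.03182) and Hoxd3os1 (0.04935) followed. Of these genes Rpl39l, Ifi35 and Serpinb6c were already called at day 0, and Rpl39l, Ifi35, Fst, Morc1, Sox18 and Myh6 at day 2.

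Probe sets that the annotation table does not list were outside the comparisons of genes. Of 9160 such probe sets other than controls 3375 passed the filter, and 440 changed on average over days 4 to 10, 240 higher and 200 lower with Sox17 shRNA. The largest rise among them was 1.91 and the largest fall -1.82 on the log2 scale.

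The first pattern weighed is the fall of cardiac contractile genes, whose list median was near 0 up to day 5 (-0.03, 0.02, -0.04 and -0.02 at days 0, 2, 4 and 5) and -2.20 over days 6 to 10. Genes near background in both arms up to day 5, as Tnnt2 was (3.49 to 4.11), cannot show a difference then. For such genes an early difference near 0 does not show that the arms were alike. Slower differentiation of all cells is argued against, since at day 10 the Sox17 shRNA arrays stood at 0.388 and 0.458 of the control's path from day 5 to day 10 for 26 contractile genes but at 0.977 and 0.973 for 1412 other genes that change along it, a mean difference of -0.552. RNA integrity and hybridisation are argued against as the whole cause, since the list median was -2.25 with the control probe sets and the spike-in as terms, with 27 genes called lower in both fits. A requirement for Sox17 in the formation of heart muscle, in its own or in other cells of the culture, may account for the pattern. It cannot be told apart from a difference between the transduced populations other than Sox17, because 1 shRNA was analysed. At day 6 the fall did not follow the Sox17 level of the array. Sox17 shRNA replicate 2, whose 3' to 5' difference was high, read 9.39 for Sox17 (control 9.83 and 9.355), and replicate 1 read 8.60. On the same path the contractile genes stood at 0.144 in replicate 2 and 0.0893 in replicate 1 (control 0.765 and 0.775). Whether lower Sox17 on earlier days matters was not tested. Days 0 and 2, which share no arrays, had 39 genes called higher at both, where independent lists would share 2.324. They had 22 called lower at both, against 1.003, and 1 called in opposite directions. Day 0 shared 38 higher with day 4 (against 4.997), 55 with day 5 (9.228), 40 with day 6 (4.253) and 36 with day 10 (8.427). For these days it shared 7 (1.831), 10 (3.274), 9 (2.385) and 7 (4.428) lower, with 4, 5, 6 and 9 opposite. Day 0 shared fewest with day 8, 14 higher (against 2.831) and 2 lower (against 2.962), with 6 opposite. Part of the day 0 difference, which rests on 1 Sox17 shRNA array, thus recurred at day 2 and, for genes called higher, at each later day. The bearing of this overlap on the contractile genes was not tested. Of the 251 genes that differed at day 0, by 1 Sox17 shRNA array, 70.5% (177, of which 111 called) had the same direction on average over days 4 to 10, which does not by itself back such a difference, since 703 of 7776 assignments of the arrays within those days gave as much (exact one-sided p = 0.0904), and the share was 54.0% for the 76 genes called without control day 0 replicate 2.

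The second pattern is the higher level of primitive streak genes at day 5. It did not come from the array with the raised spike-in signal alone, since the list median against the control arrays was 0.63 in replicate 2 and 1.15 in replicate 1. Sox17 itself differed from the control mean by -0.30 in replicate 2 and -2.61 in replicate 1. A delay of all cells between days 4 and 5 could produce it and cannot be told apart from a longer streak stage. On the control's path from day 4 to day 5 the Sox17 shRNA arrays stood at 0.0788 and 0.249 for 10 streak genes and at 0.131 and 0.546 for 306 other genes, a mean difference of 0.175 with unlike replicates.

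The third pattern is the higher level of blood genes over days 6 to 10, with a list median of 0.74 (0.06 at day 2, camera adjusted p = 2.3e-06, and adjusted p = 0.154 with an estimated correlation), which no single array decides, as the lowest median with 1 left out was 0.62 (without Sox17 shRNA day 10 replicate 1). A lower share of heart muscle cells would raise the markers of all other cell types alike. The arm difference of each array's list median was put to an exact two-sided test across the 6 arrays per arm (216 assignments within days). Visceral endoderm (-0.91, exact p = 0.00926, the smallest possible, below both control arrays of the day in 6 of 6) and neural genes (-0.23, exact p = 0.0278, 5 of 6) were lower. Fibroblast (0.52) and trophoblast genes (0.40) were higher (exact p = 0.00926 each). Adjusted over the lists so tested, the exact p was 0.0324 for neural genes and 0.0162 for the others named. A lower share alone thus does not account for all these lists. A list may fall for a reason of its own, so whether a lower share raised the blood genes cannot be told. Endothelial genes (-0.39) missed the exact test (exact p = 0.0833, 4 of 6), and with an estimated correlation camera called none of these lists (adjusted p = 0.118 for visceral endoderm, 0.113 for neural, 0.118 for fibroblast, 0.154 for trophoblast and 0.380 for endothelial genes). The bound was set 3 times: 2 of 3 lists lower by camera, which was met, then endothelial and visceral endoderm genes each lower by the exact test, which was not, and, once these p-values were seen, lists that move apart in both directions, which was met. A bound chosen in view of its p-values does not count against the explanation. More blood cells may account for the pattern, as a hypothesis without a test of its own. A lower share of heart muscle cells stays open, as does, here too, a difference between the transduced populations other than Sox17.

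Other assignments of the arrays to arms within each day were drawn, 100 with the real one. For the average over days 4 to 10 chance in the assignment of arrays within days can be excluded. Only the real assignment (1 of 100) gave as many as its 3593 genes (highest other 1310). These assignments treat arrays of different days as independent. A difference between the transduced populations that lasts over the days would pass this count, so it is not excluded. For the dependence on the day chance cannot be excluded by this count. There 7 of 100 gave as many as the real 798 genes (highest other 1862, and 4 with over 1.5 times the real number). In all 6 others whole arms were exchanged at some days and not at others, with arrays mixed at 1 to 3 of the 6 days. Such an exchange turns the sign of the difference at those days, so these assignments carry a structure of the samples. For the lists, 5 of 100 gave as many as the real 16 (highest other 17), so chance is not excluded for their number.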

How the results depend on the processing

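The hybridisation term, the arrays left out for their spike-in or 3' to 5' difference, the average over days 6 to 10 and the subtraction of day 2 were chosen only after the data were seen. Of the counts and other leading values, 173 stayed within 1.5 times or on their side of the threshold, 18 became stronger and 23 weaker. With 1 array left out 111 stayed so, 2 became stronger and 21 weaker. A count has no direction, so that 0 reversed says something of the Sox17 level alone. The balance of higher and lower genes among those called did turn at several days. Of 365 called values of single genes, 4750 of 4986 recalculated values kept the call, 228 lost it and 8 reversed, and with 1 array left out 3119 of 3280 kept it. Apart from leaving out 1 array, at least 1 alternative took the call from 114 of the 365 values. With array weights 1242 genes were called at day 0, 821 at day 2, 10 at day 4 (906 at an unadjusted p under 0.05), 1063 at day 8, 2866 at day 10 and 1291 by the F test. The cause of this change was not tested. Requiring a log2 difference of at least 1, which can only lower a count, left 92, 78, 168, 270, 226, 289 and 431 genes at days 0 to 10, 168 on average and, for the control against day 0, 1200, 2121, 2885, 3298, 3998 and 4002. With only the arrays compared, where the spread comes from those arrays alone, limma called 2111 genes at day 0, 798 at day 2, 0 at day 4 (1034 at an unadjusted p under 0.05), 244 at day 5, 328 at day 6 and 335 at day 8. With the hybridisation term they were 536 at day 0, 583 at day 2, 1103 at day 4 and 1224 by the F test, and the control counts 5008, 5745, 5325, 5714, 6772 and 6676; the cause was not tested. Without the 3 arrays of high spike-in signal at days 4 and 5 there were 352 genes at day 4 and 660 at day 5 from fewer arrays, while the average gave 3709 and the lists 17. Without the 2 arrays of the highest 3' to 5' difference 1369 genes were called at day 4 and 1440 by the F test; the cause was not tested. The average less the day 2 difference called 313 genes; it both takes away the day 2 difference and adds its error, and these were not separated. With it Klf4 (0.023), S100g (0.023), Col4a2 (0.067), P4ha2 (0.41), Hmox1 (-0.10), Dnajb1 (-0.12) and Gdf3 (-0.20) reversed, and over days 6 to 10 Wnt6 (-0.029) did, none of them called there; the cause was not tested. With an estimated correlation 1 list passed. Leaving out 1 array gave 76 to 152 genes at day 0, 68 to 152 at day 2, 216 to 1217 at day 4, 315 to 1710 at day 5, 229 to 652 at day 6, 309 to 704 at day 8, 540 to 1007 at day 10, 3075 to 4121 on average and 529 to 1244 by the F test, 14 to 19 lists, and -2.38 to -1.61 for Sox17 on average. An arm left with 1 array is assumed to vary like the other groups. No scaling moved the median of all genes by over 0.1 in the comparisons of the arms, and lists changed sign only where they were not called. The number of arrays, and for silent genes the signal over background, limit what single days can show.

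The labels number the replicates in both arms, and the numbers were not taken to pair the arrays, as a pairing needed every correlation to be over 0.1. Deviations from the group means correlated between same-numbered arrays of the arms at 0.129, 0.683, 0.22, 0.117, 0.103 and 0.0986 at days 2 to 10, and 28 of all 78 pairs of groups lay over 0.1. At day 4 the same-numbered arrays also shared their spike-in signal, so that there the block removes that difference too. With the replicate number as a block within each day, 584 genes were called at day 2, 1193 at day 4, 1887 at day 5, 1125 at day 6, 1924 at day 10, 4433 on average and 1316 by the F test. With it as 1 term over all days the average gave 3874.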

Other observations

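The tests of megakaryocyte and mesothelium genes, and the genes named in this part, were chosen only after the result was seen. Genes with large differences at day 10 included some not yet described. Higher with Sox17 shRNA were Col14a1, a fibril-associated collagen, 7.93-fold (2.99, SE 0.29, limma adjusted p = 1.6e-06), the small proteoglycans Fmod (5.15-fold) and Dcn (4.59-fold), and the lung mesenchyme ligand Wnt2 (4.06-fold). Lower were Foxd1, a forkhead factor of kidney stroma and retina (-3.46, SE 0.18, adjusted p = 8.1e-10), Gkn2, a gastric protein (-3.71), the semaphorin Sema3d (-2.89), tissue factor F3 (-3.21) and the hypoxia-inducible factor Epas1 (-2.97, adjusted p = 2.8e-06). At day 8 the erythroid genes Klf1 (2.17), Gata1 (1.84), Slc4a1 (1.85) and Kel (1.94) were higher, and at day 10 none of these passed (0.45, 0.76, 1.03 and 0.77, with adjusted p from 0.0836 to 0.653). The difference between these days was not tested.

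At day 10 the platelet chemokines Pf4 (2.62, SE 0.40, adjusted p = 2.5e-04) and Ppbp (2.68, SE 0.22, adjusted p = 2.4e-07) were higher with Sox17 shRNA. More cells of the megakaryocyte lineage are a candidate explanation, tested on a list of other genes of that lineage drawn up afterwards. Of its 13 measured members 7 were higher and none lower, with a median of 0.65 (camera adjusted p = 7.0e-05 over 8 tests of both lists, and adjusted p = 0.12 with an estimated correlation). Values of 3 members, Itga2b, Vwf and Thbs1, had been seen by then, and the other 10 had a median of 0.53 with 6 higher (camera adjusted p = 1.1e-04, and adjusted p = 0.0352 with an estimated correlation, over both lists). Itga2b rose from a log2 level of 6.26 to 7.51 and Clec1b from 5.96 to 7.40. The members with the highest signals, which many cells express, read 11.3 and 11.6 for Rap1b, 10.9 and 10.7 for Cd9 and 9.85 and 10.7 for Thbs1 in control and Sox17 shRNA arrays. Fixed lists hold 3 of the 13 genes, and cells were sorted only before aggregation, which would not remove such cells.

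The mesothelial genes Upk3b (2.34), Bnc1 (3.20) and Wt1 (1.75, adjusted p = 2.4e-05) were higher at day 10 as well. More mesothelial cells might account for them, but the 13 measured members of a list of other mesothelium and epicardium genes had a median of -0.13, with 2 higher and 2 lower (camera adjusted p = 0.992). The bound first set, a median at or below 0 or a camera p of at least 0.05, would have counted this against the hypothesis. It was loosened once the result was seen, because members that go both ways around a median near 0 decide nothing, so the hypothesis stays open and the list gives it no backing. Values of Sema3d, Gata6 and Krt19 had been seen by then, and the other 10 had a median of -0.14 (adjusted p = 0.674). The members with the highest signals, each from its own probe set, read 10.5 and 10.3 for Podxl, 10.2 and 9.74 for Igfbp5 and 9.57 and 10.5 for Gata6 in control and Sox17 shRNA arrays. Fixed lists hold 2 of the 13 genes.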
